A study of Gallus gallus with 6 samples.

How the data were processed

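Gene expression was measured by RNA-seq in the ceca and the interceca of chick embryos, with 3 libraries of each tissue. Per the labels' protocols, both regions were dissected from guts at embryonic day 5 (Hamburger-Hamilton stage 26), RNA was extracted with Trizol, and libraries were made with a strand-specific kit from NEB. The labels do not say whether the libraries of a tissue came from separate embryos or pools, so p-values measure only the spread between these samples, which may be technical.

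The values analysed are the authors' RPKM, reads scaled by gene length and library size, 1 deposited file per library. Per the submitters' processing notes, bcl2fastq, STAR, HTSeq and edgeR were used with genome build galGal4. Their roles, versions and settings, the annotation and whether counting used the strand are not given in the sources used here. An overlapping or antisense gene is therefore uncertain beside its partner. A deposited table of the whole series holds the same RPKM columns, and all 6 per-library files equal it. Its name says FPKM and its header RPKM. It also holds the authors' own comparison, with a log2 fold change of ceca over interceca, p-values before and after adjustment, and the -log10 of the adjusted p-value, per the file headers. The direction of the deposited log2 column was settled from the RPKM columns. Each file lists 17108 genes and 1 row without a gene name, the column total, which was left out. Of the genes, 3386 have only an Ensembl identifier in place of a symbol. A table of gene names for another assembly (GRCg7b) was used only to match older symbols, and no coordinates were used.

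RPKM are not counts, so a count model was not fitted. Each gene's 6 RPKM are whole multiples of a step set by its length and the library size, and this gave back whole reads, within a tolerance of 0.01 read, for 99.1% of the 14080 genes above 0 in any library and for 99.2% of the genes tested. Recovered reads in genes ranged from 15570465 to 22592885 per library. The limit that a count of 0 allows was set at 3 reads. Several genes used by most cells or expected in gut are at exactly 0 in every library, so such a gene is described only as listed at 0.

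Genes with at least 1 RPKM in at least 3 of the 6 libraries were tested, 10678 in all. The values were compared as log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, tissue as the only term), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are ceca over interceca on the log2(RPKM + 0.5) scale, which understates the change of low genes, and are given with their standard error (SE). RPKM are given as mean ± SD with 3 libraries per tissue. The fit has 4 residual degrees of freedom and a prior of 3.85. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

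Before the data were examined, 27 gene lists with 555 genes were fixed, and 475 of these genes were found in the files, 18 of them under an older symbol. The 25 lists with at least 3 tested members were compared with all other genes by limma's camera, with a preset correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation and fry were run beside it. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone.

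The genes named in the text follow a rule also fixed before the data were examined. It takes the 10 genes with the highest and the 10 with the lowest log2 fold change among those past the threshold, with a symbol, a mean of at least 2 RPKM in the higher tissue and no overlap between the tissues' libraries. It adds 30 genes chosen for their known roles, whatever their result, and up to 4 members of each list in each direction with the smallest p. Some genes that the rule takes are not reported here. Genes outside this rule are said to be chosen after their values were seen.

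The same fit was tested on simulated reads for 10588 genes of the comparison of ceca with interceca, drawn with a dispersion of 0.00269, with 200 genes changed by known folds. It recovered 59 of 67 genes changed 1.5-fold, 65 of 67 changed 2-fold and 65 of 66 changed 4-fold, and 13 of the 202 genes it called were unchanged ones. Every simulated gene had the same dispersion, a median over well-covered genes. The shares recovered therefore do not carry over to genes that vary more between libraries.

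The replicate numbers 1 to 3 are shared by the tissues in the labels. Deviations from the tissue means correlated between same-numbered libraries, across genes, at 0.364, 0.227 and 0.213, each above the highest with another number (-0.167, 0.031 and 0.031). The numbers were therefore taken to pair the samples, from the data and not from a statement in the labels. Deviations cancel within a tissue, so the values with another number are not an independent baseline and the pairing stays an assumption. The fit fixed beforehand has no block, and the fit with the replicate block is given where it changes a call.

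The alternatives were other pseudocounts, filters and scalings, the replicate block, no trend, library weights, a fold limit of 1.5, camera with an estimated correlation, fry, and leaving out each library in turn. Limma-voom on the recovered reads was added after seeing the data. Tests meant for count files were not run because the files hold RPKM.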

Results

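Transcripts were profiled by RNA-seq in the ceca, the paired blind outgrowths of the chick gut, and in the region that the labels call interceca, at embryonic day 5 (Hamburger-Hamilton stage 26). Each tissue had 3 libraries. Reads recovered from the deposited RPKM came to 20622091, 22507408 and 21142406 in ceca replicates 1 to 3 and to 15570465, 19869775 and 22592885 in interceca replicates 1 to 3. At these depths the limit that a count of 0 allows lay between 1.33e-05% and 1.93e-05% of a library's recovered reads, counting error only. Across the 10678 genes tested, which are not independent replicates, Pearson correlations of log2 values were 0.987 to 0.991 over the 6 pairs of libraries within a tissue and 0.943 to 0.959 over the 9 pairs between tissues. The first principal component took 73.8% of the variance and separated ceca from interceca, and the second took 10.1%. On the second, replicate 1 lay at 14.29 in ceca and 13.47 in interceca, and the other libraries lay at -13.57 to -3.43.

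The comparison asked which signals and cell type markers distinguish the ceca from the neighbouring gut, in a series whose title concerns the enteric nervous system of the hindgut and Wnt signalling. The ceca had higher transcript levels of several secreted ligands. GDNF, a ligand of the RET receptor of enteric neural crest cells, stood at 55.9 ± 3.31 RPKM in ceca against 22.7 ± 4.09 in interceca (SD, n = 3 each), a log2 fold change of 1.30 ± 0.11 (SE). WNT5A, a non-canonical Wnt ligand, was at 264 ± 17.1 against 123 ± 18.5 RPKM, WNT2B at 47.9 ± 7.6 against 11.4 ± 1.82, and FGF10 at 63.7 ± 3.28 against 23.5 ± 3.37. Genes of the gut epithelium and of smooth muscle were lower in ceca, with SHH, an epithelial Hedgehog ligand, at 18.3 ± 5.3 against 70.7 ± 13.9 RPKM and MYH11, smooth muscle myosin heavy chain, at 2.84 ± 0.467 against 19.1 ± 0.832. The list of gut epithelial genes had an adjusted p = 0.484 with an estimated correlation and that of smooth muscle genes an adjusted p = 0.192 with an estimated correlation, so neither call held there. The plot of single libraries shows 12 signalling genes.

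**Figure D1:**
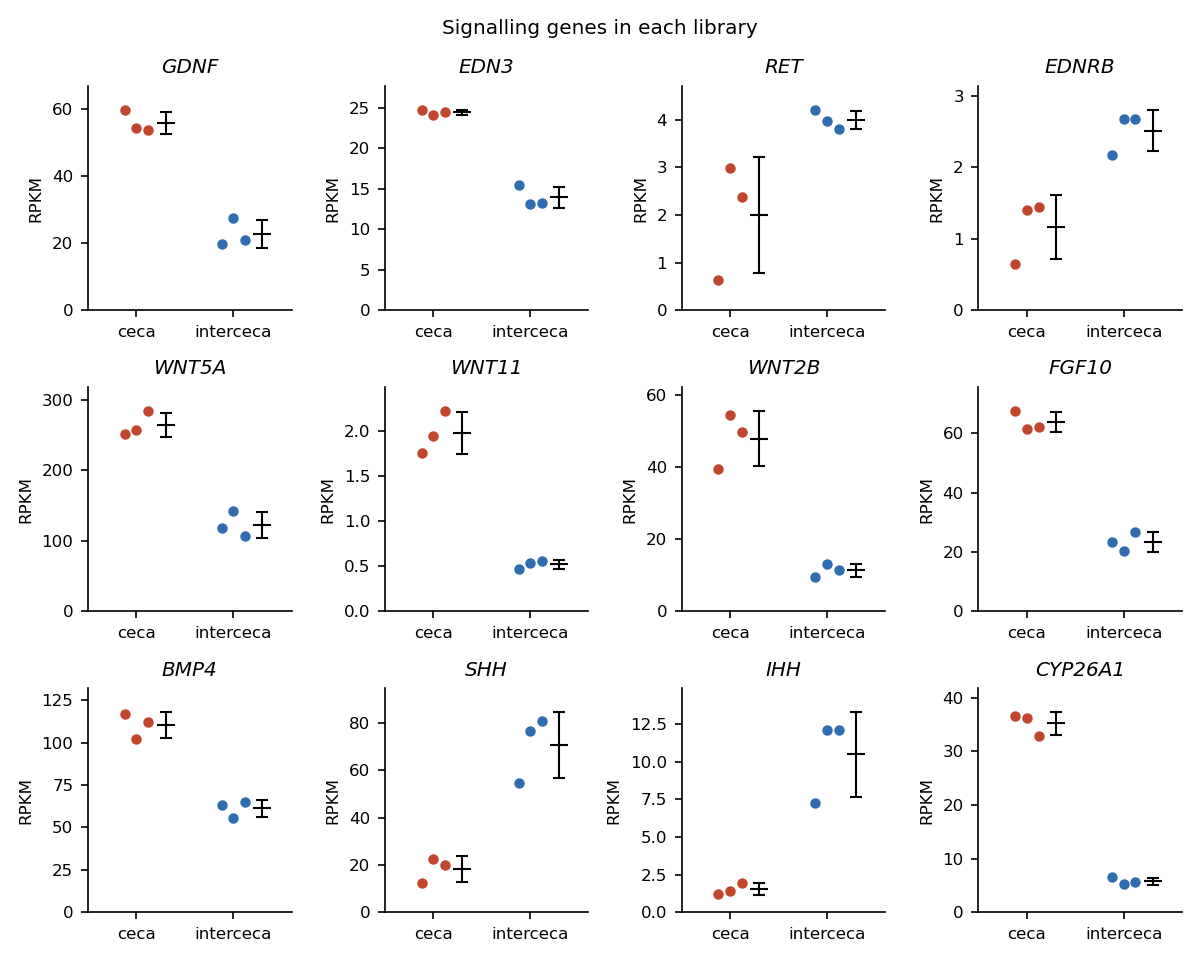
RPKM of 12 signalling genes in ceca (red) and interceca (blue), 1 point per library, with the mean and SD of the 3 libraries of each tissue in black and a separate vertical axis from 0 for each gene. GDNF lies at 53.7 to 59.7 RPKM in ceca and at 19.8 to 27.4 in interceca, and RET has a low library in ceca, replicate 1 at 0.636 RPKM.

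In all, 1439 genes were higher in ceca and 1502 were higher in interceca (limma, adjusted over all genes tested), while 7737 did not pass the threshold. In 4709 of the 10678 genes tested, 44.1%, all 3 libraries of one tissue lay above all 3 of the other, which chance gives for 10% of genes. Larger differences were more often toward interceca: 208 called genes were at least 2-fold higher in ceca and 498 in interceca, and 23 and 122 were at least 4-fold higher. With a test against a fold of 1.5 in place of 0 change, 179 genes were higher in ceca and 385 in interceca. The count higher in ceca was 900 without ceca replicate 3, and the count higher in interceca was 999 without interceca replicate 2.

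**Figure D2:**
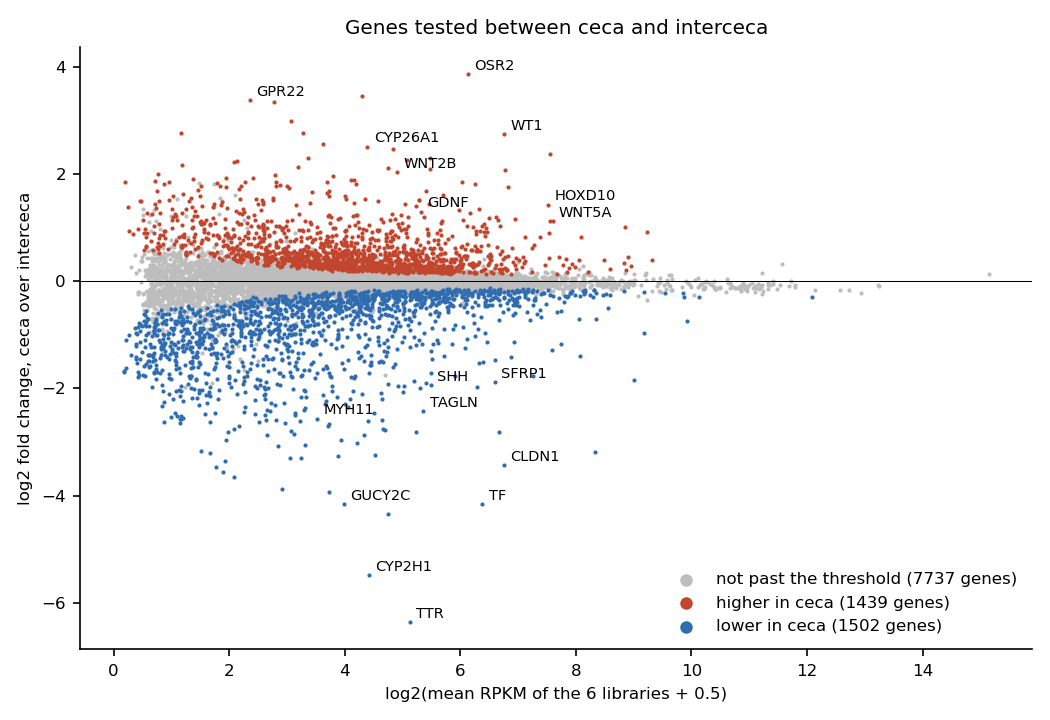
Log2 fold change of ceca over interceca against the log2 mean RPKM of the 6 libraries, plus 0.5, for the 10678 genes tested, with genes higher in ceca in red, genes lower in ceca in blue and genes not past the threshold in grey. OSR2 lies highest at 3.85 and TTR lowest at -6.35.

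Among the 10 genes furthest toward ceca that met the naming rule were the transcription factors OSR2 (log2 fold change 3.85 ± 0.20 SE, adjusted p = 1.31e-05), WT1 (2.74 ± 0.09, adjusted p = 2.38e-06) and ZFPM2 (2.55 ± 0.10, adjusted p = 3.52e-06). CYP26A1, which degrades retinoic acid, was at 35.2 ± 2.15 RPKM in ceca against 5.8 ± 0.657 in interceca, and GFRA4, a receptor of the GDNF family, at 14.5 ± 1.5 against 1.4 ± 0.171. PKIB, MDGA1, GPR22 and PXDNL had log2 fold changes of 3.46 ± 0.17, 3.34 ± 0.13, 3.37 ± 0.30 and 2.76 ± 0.18. The remaining gene, snoZ196, rested on 2, 1 and 5 reads in ceca and was listed at 0 in all 3 interceca libraries. Its adjusted p of 0.00267 was 0.0651 with limma-voom on the recovered reads, an alternative chosen after seeing the data. Among the 10 furthest toward interceca, TTR, a thyroid hormone carrier, was at 68.6 ± 1.74 RPKM in interceca against 0.404 ± 0.402 in ceca, and TF, transferrin, at 157 ± 20.6 against 8.49 ± 2.3. GUCY2C, an intestinal epithelial guanylate cyclase, had a log2 fold change of -4.15 ± 0.14 and the tight junction gene CLDN1 one of -3.42 ± 0.22. CYP2H1, ENPP6, LCAT, MASP1, PLA2 and Rd had log2 fold changes of -5.48 ± 0.31, -3.94 ± 0.17, -3.64 ± 0.18, -3.31 ± 0.11, -3.27 ± 0.23 and -3.36 ± 0.16.

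Genes of the GDNF and endothelin 3 pathways, which act on enteric neural crest cells, included 2 ligands that were higher in ceca, GDNF and EDN3. EDN3 was at 24.4 ± 0.345 against 13.9 ± 1.24 RPKM (log2 fold change 0.79 ± 0.07). The endothelin receptor EDNRB was lower, at 1.16 ± 0.45 against 2.51 ± 0.288 RPKM (-0.89 ± 0.23, adjusted p = 0.0214). Its adjusted p was 0.0748 without interceca replicate 2 and 0.0748 without interceca replicate 3, in a range of 0.00499 to 0.0748. RET was at 2 ± 1.22 RPKM in ceca and 3.99 ± 0.199 in interceca (log2 fold change -1.0 ± 0.37, adjusted p = 0.0864). With the replicate block its adjusted p was 0.0435. It was 0.0386 without ceca replicate 1, with a log2 fold change of -0.50, 0.0398 without ceca replicate 2 and 0.0407 with limma-voom, in a range of 0.0386 to 0.173 over all alternatives. Of the 9 members tested, 2 were higher, 1 was lower and 6 did not pass, against 4 higher and 3 lower adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.654, and adjusted p = 0.774 with an estimated correlation), its direction in the test being up, its median log2 fold change -0.001 and its mean -0.082. GFRA1, a GDNF co-receptor, was below the filter, at 0.697 ± 0.333 RPKM in ceca and 0.972 ± 0.26 in interceca.

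Among markers of enteric neural crest cells, TFAP2B (log2 fold change -1.42 ± 0.40), S100B (-0.91 ± 0.22) and EDNRB were lower in ceca, while FABP7 (1.11 ± 0.12) and NGFR (0.95 ± 0.13), which other cell types also express, were higher, FABP7 at 69.8 ± 10.4 against 32 ± 4.22 RPKM. The call of TFAP2B was lost in 5 of the 6 fits that left out a library, all but that without ceca replicate 2, with adjusted p of 0.0508 to 0.0937. It was also lost with no filter (0.0567) and with no trend (0.0562). The adjusted p of S100B was 0.0818 with quantile normalization. When an interceca library was left out, S100B fell below the filter and was not tested. SOX10 was at 0.791 ± 0.535 RPKM in ceca against 1.78 ± 0.465 (-0.90 ± 0.35, adjusted p = 0.0931, 0.0156 with the replicate block and 0.0478 with limma-voom, in a range of 0.0156 to 0.24 over all alternatives). Of 9 members tested, 2 were higher, 3 lower and 4 not past the threshold, against 2 higher and 6 lower adjusted over the list alone. Camera did not call the list (adjusted p = 0.323, and adjusted p = 0.699 with an estimated correlation). SOX10 and RET were lowest in ceca replicate 1, at 0.2 and 0.636 RPKM against 0.932 and 2.98 in ceca replicate 2, while FABP7 was highest there, at 81.5 against 61.9 RPKM.

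Of 14 genes of neuronal differentiation tested, 4 were lower in ceca, 1 was higher and 9 did not pass, against 10 lower and 2 higher adjusted over the list alone. The neurofilament genes NEFL and NEFM had log2 fold changes of -1.80 ± 0.42 and -1.79 ± 0.44, and the neuropeptide gene GAL one of -1.27 ± 0.31. Without ceca replicate 3 the adjusted p was 0.0572 for NEFL, 0.0665 for NEFM and 0.0626 for GAL. Without interceca replicate 1 or 3 it was 0.0575 or 0.0515 for NEFM and 0.0599 or 0.0696 for GAL, and without ceca replicate 1 it was 0.0538 for NEFM. ISL1 was lower by a log2 fold change of -0.66 ± 0.18 and DCX, a microtubule protein of young neurons, higher by 0.52 ± 0.08. The call of ISL1 was held in 1 of the 6 fits that left out a library, that without interceca replicate 2, with adjusted p of 0.0515 to 0.103 in the others. No filter (0.053) and quantile normalization (0.0553) also ended it. ELAVL4 was at 16.3 ± 2.9 RPKM in ceca against 19.6 ± 2.64 (-0.26 ± 0.13, adjusted p = 0.191, and 0.0422 without ceca replicate 2, in a range of 0.0422 to 0.427). TUBB3 was at 765 ± 64.4 against 855 ± 10.1 (-0.17 ± 0.07, adjusted p = 0.113, 0.032 without ceca replicate 1 and 0.0294 with the replicate block, in a range of 0.0294 to 0.399). The list was lower in ceca at a camera adjusted p of 0.0446, and adjusted p = 0.662 with an estimated correlation. That call was also lost with the replicate block (adjusted p = 0.0882) and without ceca replicate 1, ceca replicate 3, interceca replicate 1 or interceca replicate 3 (adjusted p = 0.143, 0.0943, 0.0694 and 0.0577). With all libraries it was lost with no filter, a filter at 5 RPKM, median-of-ratios scaling, quantile normalization and library weights as well (adjusted p = 0.0856, 0.235, 0.0542, 0.0766 and 0.0681).

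Within the non-canonical Wnt and planar polarity list, 6 of 23 members tested were higher in ceca, 4 were lower and 13 did not pass, with the same numbers adjusted over the list alone. WNT5A had a log2 fold change of 1.11 ± 0.10 (adjusted p = 0.000155). WNT11, another ligand of this kind, was at 1.97 ± 0.231 RPKM in ceca against 0.521 ± 0.0466 (1.27 ± 0.16, adjusted p = 0.00074). FZD6 (0.39 ± 0.07), VANGL2 (0.27 ± 0.06) and the WNT5A receptor ROR2 (0.26 ± 0.06) were higher by smaller amounts, and FZD7 (-1.03 ± 0.07), PRICKLE1 (-0.82 ± 0.12), GPC4 (-0.68 ± 0.05) and RYK (-0.40 ± 0.05) were lower. The adjusted p of VANGL2 was 0.0501 without ceca replicate 2, and that of ROR2 was 0.0562 without ceca replicate 1 and 0.06 without interceca replicate 3. FZD3 had a log2 fold change of 0.14 ± 0.11 (adjusted p = 0.4), and WNT4 was below the filter at 0.216 ± 0.204 RPKM in ceca and 0.566 ± 0.126 in interceca. The list was not called (camera adjusted p = 0.519, and adjusted p = 0.699 with an estimated correlation).

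Among other Wnt ligands, 1 of 3 tested, WNT2B, was higher in ceca (2.03 ± 0.14), with the same count adjusted over the list alone. The list was not called (camera adjusted p = 0.406, and adjusted p = 0.662 with an estimated correlation). Of 15 genes known as canonical Wnt targets, 7 were higher in ceca, 2 lower and 6 not past the threshold, with the same numbers adjusted over the list alone. LEF1 (1.08 ± 0.09), NOTUM (1.48 ± 0.16), NKD1 (0.44 ± 0.08) and MYC (0.32 ± 0.05) were higher, and CDX1 (-3.02 ± 0.26) and LGR5 (-0.62 ± 0.11) lower. This list was not called (camera adjusted p = 0.125, and adjusted p = 0.501 with an estimated correlation). Of 9 secreted Wnt antagonists, NOTUM and SFRP2 (0.46 ± 0.05) were higher, while SFRP1 (-1.88 ± 0.20), DKK3 (-0.57 ± 0.07) and WIF1 (-0.92 ± 0.22) were lower and 4 did not pass, against 2 higher and 4 lower adjusted over the list alone. SFRP1 was at 41.4 ± 12 RPKM in ceca against 151 ± 24.9 in interceca, and the adjusted p of WIF1 was 0.0631 without interceca replicate 2. The antagonists were not called as a list (camera adjusted p = 0.753, and adjusted p = 0.774 with an estimated correlation).

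Of 17 BMP pathway genes tested, 7 were higher in ceca, 3 lower and 7 not past the threshold, against 9 higher and 3 lower adjusted over the list alone. BMP4 was at 110 ± 7.96 RPKM in ceca against 61.3 ± 5.09 (log2 fold change 0.85 ± 0.08). BMP5 (0.73 ± 0.12) and GDF5 (0.81 ± 0.15) were also higher, whereas the ligands BMP6 (-1.96 ± 0.11) and BMP3 (-1.01 ± 0.16) were lower. Of 16 FGF pathway genes, 6 were higher, 1 lower and 9 not past the threshold, against 8 higher and 2 lower adjusted over the list alone. FGF10 (1.43 ± 0.10), FGF16 (1.54 ± 0.34) and the FGF antagonist SPRED1 (0.37 ± 0.06) were higher. FGFR2, the receptor of FGF10, was lower at 62.7 ± 3.44 against 100 ± 1.53 RPKM (-0.67 ± 0.05). Neither list was called (BMP, camera adjusted p = 0.195, and adjusted p = 0.501 with an estimated correlation, and FGF, camera adjusted p = 0.231, and adjusted p = 0.646 with an estimated correlation).

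Hedgehog pathway genes moved in both directions, with 4 of 12 tested higher, 5 lower and 3 not past the threshold, against 5 and 5 adjusted over the list alone. The ligands SHH (-1.94 ± 0.22) and IHH (-2.42 ± 0.22) were lower in ceca, as were the feedback gene HHIP (-1.02 ± 0.09) and the receptor PTCH1 (-0.41 ± 0.10). The co-receptors BOC (1.69 ± 0.13) and CDON (0.27 ± 0.05) and the effector GLI2 (0.64 ± 0.09) were higher. The adjusted p of PTCH1 was 0.0572 and 0.07 without ceca replicates 1 and 3, and 0.0589 and 0.0647 without interceca replicates 1 and 2. The list was not called (camera adjusted p = 0.852, and adjusted p = 0.903 with an estimated correlation), with a median log2 fold change of 0.054 and a mean of -0.278. Of 14 retinoic acid genes, 7 were higher, 4 lower and 3 not past the threshold, against 8 and 4 adjusted over the list alone. The synthesis enzyme ALDH1A2 (1.61 ± 0.25), the receptor RARB (1.59 ± 0.11), CRABP2 (0.91 ± 0.06) and CYP26A1 (2.51 ± 0.09) were higher, and ALDH1A1 (-2.96 ± 0.21), RXRG (-0.89 ± 0.14) and RXRA (-0.50 ± 0.07) were lower. This list was not called either (camera adjusted p = 0.265, and adjusted p = 0.501 with an estimated correlation).

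Notch pathway genes were lower in ceca as a list (camera adjusted p = 0.00188, and adjusted p = 0.383 with an estimated correlation). Of 12 tested, 6 were lower and 6 did not pass, against 8 lower and 1 higher adjusted over the list alone. The ligands DLL1 (-1.92 ± 0.12) and JAG2 (-1.71 ± 0.08) and the effectors HEY1 (-1.55 ± 0.08) and HES4 (-1.17 ± 0.07) had the smallest p.

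The Hox genes of the anterior list were higher in ceca (camera adjusted p = 0.00519, and adjusted p = 0.501 with an estimated correlation), with 6 of 9 tested higher and 3 not past the threshold, the same adjusted over the list alone. HOXD4 (1.06 ± 0.13), HOXB5 (0.76 ± 0.06), HOXB3 (0.69 ± 0.10) and HOXB4 (0.52 ± 0.08) were among them. Of 13 posterior Hox and hindgut patterning genes, 6 were higher, 4 lower and 3 not past the threshold, against 7 and 4 adjusted over the list alone. HOXD10 was at 268 ± 16.2 RPKM in ceca against 99.6 ± 12.5 (1.43 ± 0.09), and HOXD8 (1.02 ± 0.08), PITX1 (0.73 ± 0.08) and HOXB9 (0.57 ± 0.12) were higher too. CDX1, CDX4 (-1.64 ± 0.21) and HOXD12 (-2.03 ± 0.37) were among those lower. HOXD12 was at 1.85, 1.9 and 5.47 RPKM in interceca replicates 1 to 3. HOXD13, below the filter, was at 0.756, 0.595 and 3.1 RPKM in the same libraries and at 0, 0.129 and 0 in ceca. HOXD11 had a log2 fold change of 0.54 ± 0.20 (adjusted p = 0.0858), with an adjusted p of 0.0208 with the replicate block, 0.0275 with library weights and 0.00892 without interceca replicate 3, in a range of 0.00892 to 0.203. TBX5 was below the filter at 0.039 ± 0.0157 and 0.0138 ± 0.0149 RPKM and HOXA13 was listed at 0 in all 6 libraries. The posterior list was not called (camera adjusted p = 0.519, and adjusted p = 0.699 with an estimated correlation), its median of 0.524 and its mean of -0.236 having opposite signs.

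Smooth muscle genes were lower in ceca (camera adjusted p = 1.05e-09, and adjusted p = 0.192 with an estimated correlation). Of 13 tested, 11 were lower and 2 did not pass, against 12 lower adjusted over the list alone. TAGLN was at 12.4 ± 0.428 RPKM in ceca against 68.9 ± 1.26 (-2.42 ± 0.05), and MYH11 (-2.56 ± 0.11), MYL9 (-1.71 ± 0.05) and MYOCD, a coactivator of smooth muscle genes (-1.13 ± 0.06), were lower as well. ACTA2 was not analysed here. Gut epithelial genes were lower in ceca too (camera adjusted p = 1.9e-07, and adjusted p = 0.484 with an estimated correlation). Of 16 tested, 13 were lower, 1 was higher and 2 did not pass, against 14 lower and 1 higher adjusted over the list alone. GATA6 (-2.87 ± 0.25), IHH and HNF4A (-2.28 ± 0.14) were lower, and the intestinal transcription factor CDX2 was higher (0.99 ± 0.24). The adjusted p of CDX2 was 0.0555 and 0.0648 without ceca replicates 2 and 3, and 0.0559 and 0.0609 without interceca replicates 2 and 3. Genes of the foregut, liver and pancreas list were lower (camera adjusted p = 0.00261, and adjusted p = 0.28 with an estimated correlation), with TTR (-6.35 ± 0.27), FGB (-2.59 ± 0.17) and APOA1 (-1.77 ± 0.17) lower of 6 tested and 3 not past the threshold, the same adjusted over the list alone.

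Mesothelial genes were higher in ceca (camera adjusted p = 0.0446, and adjusted p = 0.484 with an estimated correlation). All 9 tested passed, 7 higher and 2 lower, the same adjusted over the list alone. WT1 was at 188 ± 13.9 RPKM in ceca against 27.8 ± 3.45, and BNC1 (0.89 ± 0.07), CRB2 (0.58 ± 0.09) and TCF21 (0.52 ± 0.06) were higher, while MSLN (-2.27 ± 0.15) and UPK1B (-2.54 ± 0.20) were lower. The call of the mesothelial list was lost without ceca replicate 2 and without ceca replicate 3 (adjusted p = 0.0535 and 0.0659). It was also lost on the TPM scale, with quantile normalization and with no filter (adjusted p = 0.0997, 0.0766 and 0.0665). Immediate early and heat shock genes, some of which respond to tissue handling, were lower in ceca (camera adjusted p = 0.0446, and adjusted p = 0.619 with an estimated correlation). Of 17 tested, 7 were lower, 2 higher and 8 not past the threshold, the same adjusted over the list alone. HSPB1 (-1.26 ± 0.06), CTGF (-1.21 ± 0.10), DUSP1 (-1.20 ± 0.12) and CYR61 (-0.83 ± 0.11) were lower and KLF2 (0.85 ± 0.10) and KLF6 (0.32 ± 0.06) higher. This call was lost with the replicate block (adjusted p = 0.0577), without ceca replicate 1 (0.143) and without interceca replicate 3 (0.0577). No filter, median-of-ratios scaling, quantile normalization and library weights also ended it (adjusted p = 0.058, 0.0542, 0.111 and 0.0975).

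Of 26 proliferation genes tested, 1 was lower in ceca and 25 did not pass, against 0 by limma adjusted over the list alone. The lower gene, AURKA, had a log2 fold change of -0.18 ± 0.05 (adjusted p = 0.0385), and its call was lost in 5 of the 6 fits that left out a library, all but that without interceca replicate 1, with adjusted p of 0.0865 to 0.114. With all libraries it was lost on the TPM scale (0.0762), with no trend (0.0663) and with limma-voom (0.0597). MKI67 was at 31.9 ± 3.35 RPKM in ceca against 27 ± 3.2 (0.24 ± 0.10, adjusted p = 0.125, 0.0434 without interceca replicate 1 and 0.0121 with the replicate block, in a range of 0.0121 to 0.327). The list was not called (camera adjusted p = 0.852, and adjusted p = 0.988 with an estimated correlation). Extracellular matrix genes went both ways, 10 of 30 tested higher, 6 lower and 14 not past the threshold, against 11 and 8 adjusted over the list alone (camera adjusted p = 0.997, and adjusted p = 0.998 with an estimated correlation). COL3A1 was at 63.8 ± 4.88 RPKM in ceca against 171 ± 18.4 (-1.41 ± 0.08). LUM (-1.29 ± 0.05), ELN (-0.99 ± 0.14) and THBS1 (-0.75 ± 0.13) were lower as well, and FBLN1 (0.68 ± 0.07), COL6A3 (0.65 ± 0.13), COL5A1 (0.58 ± 0.10) and DCN (0.39 ± 0.05) were higher. TNC (-0.16 ± 0.18, adjusted p = 0.558) and COL9A1 (-0.40 ± 0.14, adjusted p = 0.0765) did not pass. For COL9A1 the adjusted p was 0.0332 with library weights and 0.0403 with limma-voom, in a range of 0.0332 to 0.182.

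Of 33 genes of axon guidance and migration cues tested, 12 were higher, 9 lower and 12 not past the threshold, against 15 and 10 adjusted over the list alone (camera adjusted p = 0.403, and adjusted p = 0.741 with an estimated correlation). The netrin receptor UNC5A (1.73 ± 0.09), EPHA7 (1.53 ± 0.10), EPHB1 (1.01 ± 0.08) and ROBO1 (0.59 ± 0.04) were higher in ceca, and EFNB1 (-1.48 ± 0.08), NRP2 (-1.14 ± 0.05), EPHA3 (-0.97 ± 0.11) and KITLG (-0.80 ± 0.11) were lower. Of 16 endothelial genes, 4 were higher, 1 lower and 11 not past the threshold, the same adjusted over the list alone (camera adjusted p = 0.31, and adjusted p = 0.774 with an estimated correlation), with MMRN1 (0.58 ± 0.10) and FLT4 (0.41 ± 0.08) higher. Of 11 blood genes, LCP1 (1.67 ± 0.25) was higher, CD74 (-0.61 ± 0.13) and TFRC (-0.33 ± 0.07) were lower and 8 did not pass, with the same numbers adjusted over the list alone. The blood list was not called (camera adjusted p = 0.997, and adjusted p = 0.998 with an estimated correlation), with a median of -0.124 and a mean of 0.081. Of 4 mesonephros and gonad genes tested, DMRT1 (1.37 ± 0.19) and DAZL (0.66 ± 0.18) were higher and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.31, and adjusted p = 0.599 with an estimated correlation). The adjusted p of DAZL was 0.06, 0.0631 and 0.0938 without interceca replicates 1, 2 and 3. Without any 1 ceca library DAZL fell below the filter, so its call was lost in all 3 fits without a library that tested it. Of the skeletal and cardiac muscle list only 2 genes were tested, TNNC1 (-1.25 ± 0.14) and ACTA1 (-0.41 ± 0.12), and of the W-linked list 0, so neither list was compared. For ACTA1 the adjusted p was 0.068 and 0.105 without ceca replicates 1 and 2, and 0.0991 and 0.103 without interceca replicates 1 and 3. It was 0.057 with no filter, 0.0613 on the TPM scale and 0.0779 with library weights.

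**Figure D3:**
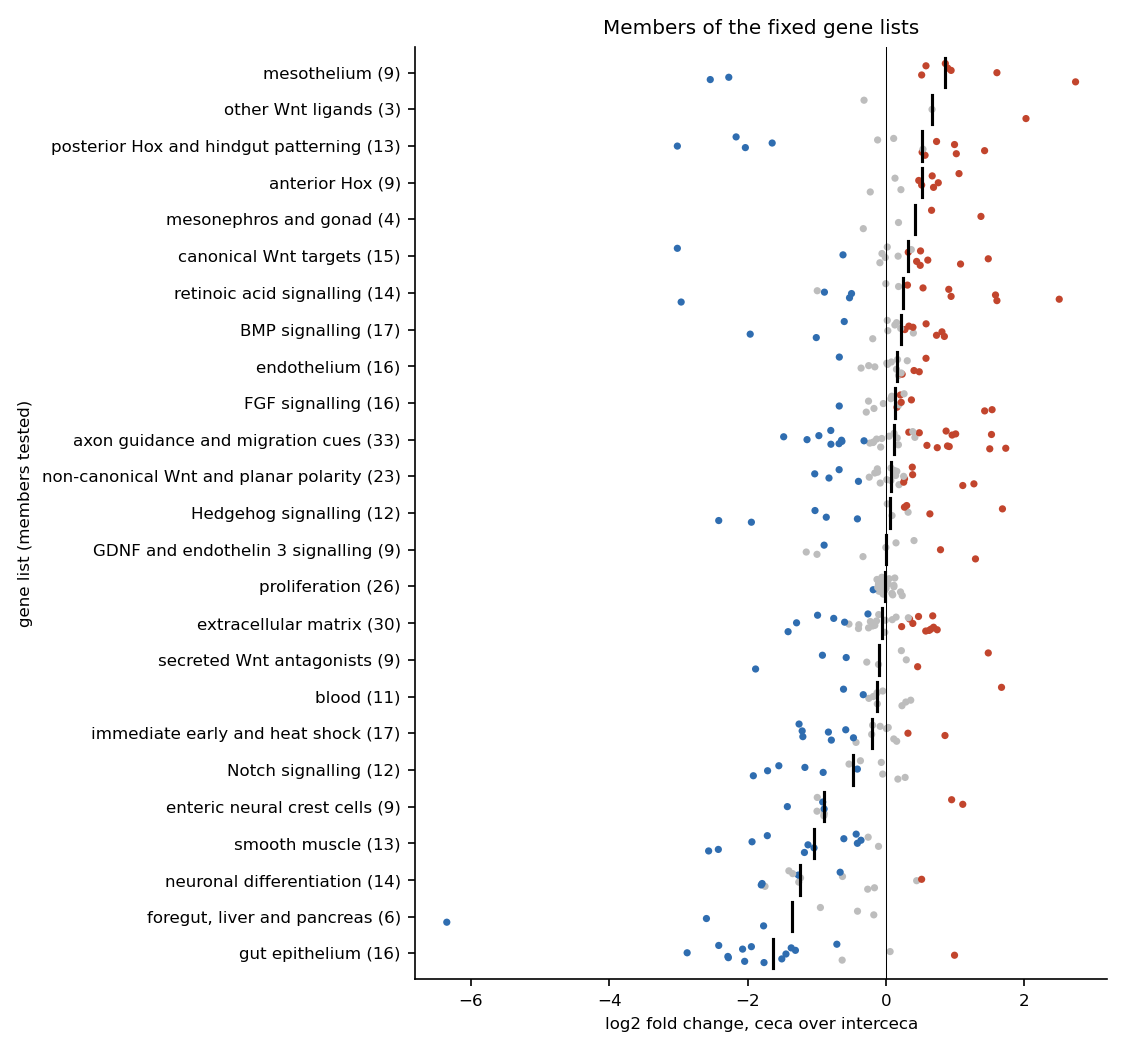
Log2 fold change of ceca over interceca for each tested member of the 25 gene lists, with members higher in ceca in red, lower in blue and not past the threshold in grey, and the median of each list as a black line. The gut epithelium, with 13 of 16 members lower, lies at the bottom and the mesothelium, with 7 of 9 higher, at the top.

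Over the 25 lists compared, camera called 8 with the preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05 and the lowest adjusted p was 0.192. Fry, which asks whether a list's genes move on balance one way and does not compare the list with other genes, called 15. Of the lists that camera called with the preset correlation, fry did not call neuronal differentiation (fry adjusted p = 0.134). Fry called the rest, at adjusted p of 6.86e-05 for smooth muscle to 0.0161 for immediate early and heat shock genes. It also called lists that camera did not, such as retinoic acid signalling (fry adjusted p = 0.0011). In the authors' deposited table, 1677 of 17108 genes were higher in ceca and 1907 higher in interceca at an adjusted p under 0.05. Of the genes tested here, the authors' deposited table called 1542 higher and 1545 lower in ceca, and 2741 of these were called in the same direction by limma. There were 346 called in the authors' deposited table alone, 200 by limma alone and 0 in opposite directions.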

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

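Limma-voom on recovered reads was the alternative chosen after seeing the data, and it called 1604 genes higher in ceca, 1577 higher in interceca and 8 lists. Against 1439 and 1502 genes, the other alternatives that tested for any change with all libraries called 1246 to 1879 higher in ceca and 1087 to 1888 higher in interceca, and the series table's columns hold the same values. The balance turned toward ceca on the TPM scale, with 1726 against 1320, with quantile normalization, with 1581 against 1421, with a filter at 5 RPKM, with 1246 against 1087, and by less with library weights and limma-voom. A test against a fold of 1.5 called 179 and 385, since small differences no longer count. Leaving out a library gave 900 to 1286 genes higher in ceca and 999 to 1316 higher in interceca, with fewer samples. Against 8 lists, 5 were called with no filter on low values, 5 with quantile normalization, 0 by camera with an estimated correlation, 15 by fry in its directional form and 25 in its mixed form, which ask other questions, and 6 to 8 without a library. The cause of the loss with no filter and with quantile normalization was not tested. With the replicate block, which uses the pairing, 1879 genes were higher in ceca, 1888 were higher in interceca and 6 lists were called, and no call of a named gene or list changed beyond those given in the report. Of the 1439 genes higher in ceca, 888 were called again without ceca replicate 3. Of the 1502 higher in interceca, 968 were called again without interceca replicate 2. Many of the 161 named genes tested were picked by their fold or p in the main fit, so their stability does not describe all calls. Of their values, 1709 of 1747 with all libraries and 841 of 924 without a library stayed on the same side of the threshold in the same direction. Of the list values 300 of 348 and 142 of 150 did. The exception in direction was TNC, not called, at 0.01 without ceca replicate 1, with a range of -0.26 to 0.01 over the fits that left out a library, and the cause was not tested. The tests for count files were not run. At 15570465 to 22592885 recovered reads per library, genes such as snoZ196, with 5 reads or fewer, are limited by depth.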

Other observations

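The ratio, level and rank tests, the medians over crest and neuronal genes and the splits in this part were chosen only after the results were seen.

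The following genes outside the fixed lists were chosen after their values were seen, because they were high in ceca, and other Wnt pathway genes outside the lists were not counted. RSPO3, a secreted enhancer of Wnt signalling, was at 47.6 ± 4.95 RPKM in ceca against 8.43 ± 2.31 in interceca (SD, n = 3 each), a log2 fold change of 2.46 ± 0.18 (SE). The receptors FZD4 (1.84 ± 0.08) and FZD10 (1.77 ± 0.13) and the pathway gene DACT2 (1.88 ± 0.08) were higher as well. WT1-AS_7, annotated as antisense to WT1, was higher by 2.23 ± 0.30, and its reads cannot be told from those of WT1 unless counting used the strand. KRT8, KRT18, GLI1, RARA, HOXA7, HOXA11 and HOXC9 were listed at 0 in all 6 libraries.

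In the gut epithelium list 13 of 16 members were lower in ceca and CDX2 was higher (0.99 ± 0.24), with an adjusted p = 0.484 with an estimated correlation, and in the foregut, liver and pancreas list TTR, FGB and APOA1 were lower, with an adjusted p = 0.28 with an estimated correlation. Liver tissue carried into the interceca libraries would bring ALB, APOB, FGG and AHSG, and the highest of these was 0.0061 of TTR there. ALB, below the filter, was at 0.415 ± 0.0644 RPKM in interceca and 0.594 ± 0.0624 in ceca, while TTR was at 68.6 ± 1.74 in interceca. The 4 genes were picked after their values were seen, and FGG had 5, 1 and 2 interceca reads where FGB had 282, 513 and 519. Genes expected in gut were also listed at 0, so values near 0 cannot rule out carried liver tissue. Whether a lower share of epithelium in ceca, which would lower its genes alike, accounts for the list alone cannot be told apart here, since the number of members with a changed log2 ratio to EPCAM (linear model, adjusted over the members) depends on how the spread is estimated. Of all 15 tested members 5 changed with limma's moderated spread, which treats it as known, 2 with that spread on the 4 residual degrees of freedom and 9 with each member's own spread, and of the 12 that were lower 2, 0 and 5 did. CDX2 and SOX9 were among those changed under each spread, at 2.75 and 1.82. A lower share alone would have lowered both, unless other cells also express them, and neither was lower. The 12 were picked by their own fall, so their counts leave out such members. Members that other cells also express would follow the share less closely, and lower epithelial expression in ceca also stays open.

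Genes of enteric neural crest cells and neurons lay mostly below 0, with a median log2 fold change of -0.91 over 23 members and quartiles of -1.31 and -0.45. How much of this a single ceca library with few crest-derived cells accounts for cannot be told apart here. Without ceca replicate 2 the median was -1.21, with quartiles of -1.83 and -0.55, and without ceca replicate 3 it was -1.08. Both lie further from 0 than with all libraries. In the fits that left out an interceca library it was -1.0 to -0.93, over 22 members. Without ceca replicate 1 the median moved to -0.64, with quartiles of -0.85 and -0.33, so most members still lay below 0. The fold of RET moved to -0.50, with a limma adjusted p of 0.0386. The call of the neuronal list was lost there (camera adjusted p = 0.143), but that loss does not single out this library. The call was also lost without ceca replicate 3, interceca replicate 1 or interceca replicate 3 (0.0943, 0.0694 and 0.0577), and with an estimated correlation (adjusted p = 0.662). The members past the threshold and lower numbered 7 with all libraries, 6, 14 and 2 without ceca replicates 1, 2 and 3, and 3, 4 and 1 without interceca replicates 1, 2 and 3. Those higher numbered 4 without ceca replicate 1 and 3 in each of the other fits. When an interceca library was left out, S100B fell below the filter, so these fits tested 22 members. A lower share of crest-derived cells in ceca and a difference in neuronal differentiation between the tissues also stay open, and no test that bears on either is reported here.

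HOXD12, HOXD13 and HOXB13 were highest in interceca replicate 3, with 295 reads together against 62 and 79 in replicates 1 and 2, that is 67.7% of the reads in a library holding 39.1% of the sum of sizes. These genes were picked because they were high there, so whether the excess lies beyond the spread between dissections was not tested. More posterior tissue in that dissection is a candidate explanation, under which the excess of replicate 3 would rise along the HOXD cluster. Spearman's rho from HOXD8 to HOXD11 was 0.80 (exact p = 0.33), and 4 genes are too few to decide. Without interceca replicate 3, 1046 genes were higher in ceca and 1017 higher in interceca.

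The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 2941 genes, and it is 1 of 10 with as many, while the highest of the other 9 called 0 (limma, with up to 547 genes at an unadjusted p under 0.05 against 4160 in the real split). The 3 other splits that part all 3 pairs also called 0. Each of the other 9 has libraries of both tissues on each side, so the tissue difference adds to the spread within sides. Few or no calls were therefore likely there in any case, and the contrast with the real split is no test of chance.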
